A study of Mus musculus with 4 samples.

How the data were processed

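Gene expression was measured by droplet single-cell RNA sequencing (10x Genomics Chromium, 3' kit, version 2 chemistry per the labels' protocols) in 4 libraries of mouse embryonic hindlimb cells, 1 per stage from E11.5 to E18.5. The deposited values are counts of UMIs per gene and cell barcode, made by the authors with Cell Ranger against genome build mm10, per the submitters' processing notes; the version of Cell Ranger and the rule by which cell barcodes were called are not given in the sources used here. Seurat 2.3.4 is also named in the submitters' processing notes, but the values read here are whole numbers with totals that differ between cells, as checked on the files, so no normalisation had been applied to them. The tables held 10272 barcodes, 33456 gene entries, 21836 of them with a UMI, and 107956574 UMIs. Gene positions and transcript lengths came from GENCODE vM21 on GRCm38 (mm10), in which 32655 of the gene IDs were found; every gene whose position is given is annotated there as protein-coding.

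Cells with at least 200 genes and at most 10% of UMIs from mitochondrially encoded genes were kept. The limit on mitochondrial UMIs removed 43 barcodes at E11.5, 68 at E13.5, 110 at E15.5 and 93 at E18.5, and the limit on genes removed 0. Scrublet in scanpy called 32 barcodes as doublets (0.311%), which were left out; so low a share is not taken as a working call, and doublets are treated as still present. Whether barcodes had been filtered for doublets before deposit is not given in the sources used here. In all 9929 cells were kept. Median genes per cell were 3238 at E11.5, 2960 at E13.5, 2793 at E15.5 and 2040 at E18.5, and the median mitochondrial share 2.60%, 2.74%, 2.91% and 3.54%. Counts were scaled to 10000 per cell and log-transformed, and 2000 highly variable genes, 30 principal components, 15 neighbours and Leiden clustering at resolution 1.0 gave 29 clusters over the 4 libraries together. No batch integration was applied, because stage and library coincide. Clusters were named from 20 lists of cell type markers written before the data were examined, on at least 3 markers found in at least 20% of cells and at least 2-fold above the other cells. Among lists that met this the one with the highest mean score gave the name. A cluster stayed unnamed where another list scored higher by over 0.5, where none of its own and at least 2 markers of another list were among its 10 leading genes, or where its median UMI count was under 1/3 of that of its library with none of its own among them. Classes are written as "like", since the name rests on markers alone. The clusters gave 13 named classes, none of them erythroid.

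With 1 library per stage nothing was tested between stages. For each of 3 successive pairs of stages, and for E18.5 over E11.5, UMIs of kept cells were summed per library and divided by their total without globin genes, giving 26831618, 35067884, 29607095 and 14663977 UMIs as the totals behind counts-per-million (CPM). Ratios have exact 95% intervals from the conditional binomial distribution, shares exact Clopper-Pearson intervals and levels exact Poisson intervals. All of these cover counting error only, and not the variation between embryos, litters or library preparations. Intervals of ratios and levels treat each UMI as independent, so they also leave out variation between cells and are too narrow where few cells hold the UMIs. A gene was called higher or lower by size: a ratio of CPM of at least 2 in either direction, the whole interval on the same side of 1, and at least 20 UMIs in the pair together. A fold against 0 UMIs is given as a bound computed with 3 UMIs in that library, and a share of 0 with the limit that 3 counts give. The ratio of the median gene was far from 1 in some pairs, so printed folds and list medians are divided by it, while counts of genes use CPM and are given with the counts relative to the median gene where these move the share of higher among called genes by over 10 percentage points or turn the larger side. The same ratios were taken within each class with at least 30 cells in both libraries, unless a cluster of the class had more leading markers of another class than of its own. Pericyte-like cells and limb bud mesenchyme-like cells were left out of this step because no pair of libraries held 30 of them each, and osteoblast-like and melanocyte-like cells for the same reason.

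Genes and lists were fixed before the data were examined. There were 29 gene lists: limb bud patterning, hindlimb identity, HoxA and HoxD, early embryonic growth programme, cartilage matrix, chondrogenic regulators, hypertrophy, joint, osteoblast, tendon, fibrous matrix, myogenic regulators, sarcomere, simple epithelial keratins, stratified epidermis, G2/M, S phase, cell cycle exit, imprinted growth, immediate early and heat shock, glycolysis and hypoxia, macrophage, endothelium, pericyte and smooth muscle, neural crest and Schwann, adipocyte, mitochondrially encoded genes, and the embryonic and adult globins. The genes named are the up to 4 members of a list with the largest ratios in either direction among those with at least 100 UMIs in the pair, the 10 highest and 10 lowest ratios of each pair among genes of at least 100 CPM in 1 of the libraries (5 and 5 within a class), leaving out globin, mitochondrial, ribosomal protein and sex-linked marker genes, and the genes of the detection comparison. A gene named for 1 pair may be given for others. A list's median log2 ratio carries an interval from 500 Poisson draws of its counts and a percentile among 10000 random lists of the same size matched on expression in 20 bins, which describes the list and is not a test. Shares of cells with a UMI were taken after thinning each cell to 2000 UMIs.

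The ratio and its size rule were tested on simulated data, made by drawing 2 libraries from 1 expression profile with 200 genes altered. The total of each gene in a library was a Poisson draw, without variation between cells or library preparations. The shares called below therefore hold for counting error alone. At a made fold of 3 the rule called 100% of altered genes for E13.5 over E11.5 and 94% for E15.5 over E13.5, with 0.334% and 0.385% of unaltered genes called. Within classes at E18.5 over E15.5 the same fold was called for 82% in chondrocyte-like and 74% in endothelium-like cells, with 1.08% and 1.76% of unaltered genes called. At a made fold of 2, the limit of the rule, 50% and 46% were called in the whole-library pairs, and 42% and 32% in these classes. Alternatives named before the data were examined were a stricter cell filter (at least 1000 genes, at most 5% mitochondrial UMIs) and none, Scrublet calls kept, Leiden resolutions of 0.5 and 2.0, each library clustered by itself, class by the highest marker score of each cell, median-of-ratios size factors, no filter on low counts, the mean over cells in place of the sum, globin genes kept, and thinning to 1000 UMIs or none. Chosen after seeing the data were leaving out the 3% of cells with the highest Scrublet scores, leaving ribosomal protein and mitochondrial genes out of the totals, centring log2 ratios on genes of like transcript length in 20 bins, taking, in a class of several clusters, only the largest cluster with at least 30 cells in both libraries, and leaving out of a class each cluster with under 5% of its cells in 1 library and at least 20% in the other. Computation used Python 3.11.15 with scanpy 1.11.5, anndata 0.12.19, igraph 0.11.9, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0 and matplotlib 3.10.9.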

Results

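The libraries hold single-cell transcriptomes of the hindlimb of C57BL/6 mouse embryos at 4 stages, which the labels tie to formation of the limb bud (E11.5), of cartilage condensations (E13.5), to joint cavitation (E15.5) and to joint morphogenesis (E18.5). Each stage is 1 library, made from the pooled hindlimb cells of a litter that had been digested with collagenase and pronase, frozen, thawed and cleared of dead cells. The count tables held 2683 barcodes at E11.5, 2884 at E13.5, 2708 at E15.5 and 1997 at E18.5, with 27149328, 35485783, 30240499 and 15080964 unique molecular identifiers (UMIs, each standing for a captured transcript). After filtering, 2630, 2812, 2591 and 1896 cells were kept, with median depths of 8926, 10260, 9934 and 6944 UMIs per cell. With 1 library per stage there was no replicate check and no test between stages could be made, so each difference compares these libraries and not the stages as such. Ranges in parentheses are 95% intervals that cover counting error only, and counts of genes called higher or lower follow a fixed rule of size.

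The first question was which cell classes made up the hindlimb at each stage. Clusters 0 and 1, with limb bud mesenchyme markers such as Lhx2, Prrx1 and Pitx1 among their leading genes, held 31.8% and 12.2% of kept cells at E11.5. Cluster 2, whose 10 leading genes, among them Hsd11b2, Tbx18 and Osr2, hold 1 marker of the joint list and none of limb bud mesenchyme, but which had 8 markers of the latter by the naming rule, held 24.6%. Together these came to 68.6% (66.8 to 70.4%), and no cell of the later libraries fell in them. When each library was clustered by itself, limb bud mesenchyme-like clusters held 19.1% at E11.5, 11% at E13.5 and 5.25% at E15.5. By highest marker score the E11.5 share was 37.0%, so both this share and the absence of such cells from later stages depend on how cells are classed. Chondrocyte-like and hypertrophic chondrocyte-like cells together held 48.1% (46.3 to 50.0%) at E13.5, 52.6% (50.7 to 54.5%) at E15.5 and 15.6% (14.0 to 17.3%) at E18.5. Muscle-like cells, both progenitors and differentiating cells, held 0.266% (0.107 to 0.548%), 2.49% (1.95 to 3.13%), 5.17% (4.35 to 6.10%) and 22.5% (20.7 to 24.5%) at the 4 stages in order. With each cell in the class of its highest marker score the share was 0.608% at E11.5 and 12.1% at E18.5, and with the 3% highest Scrublet scores left out 0.742% at E11.5. Pericyte-like and smooth muscle-like cells, the contractile cells of vessel walls, held 0.502% (0.267 to 0.857%) at E15.5 and 17.9% (16.2 to 19.7%) at E18.5, but 0% at E15.5 with each library clustered by itself.

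Hypertrophic chondrocyte-like cells, which enlarge before bone replaces cartilage, held 6.26% (5.39 to 7.22%) at E13.5, 4.90% (4.10 to 5.80%) at E15.5 and 1.16% (0.729 to 1.75%) at E18.5. With each library clustered by itself the order of the earlier stages turned, with 3.95% at E13.5 and 7.99% at E15.5, and by highest marker score the E15.5 share was 9.07%. Joint-like cells, named from Gdf5 and other genes of the future joint, held 9.42% (8.37 to 10.6%) at E13.5, 3.98% (3.26 to 4.80%) at E15.5 and 0% (up to 0.158% allowed by a count of 0) at E18.5. The shares by separate clustering were 10.1% at E13.5 and 8.68% at E15.5. Those at Leiden resolution 0.5 were 18.3% and 10.7%, and the E13.5 share was 15.3% with the Scrublet calls kept. A cluster named chondrocyte-like held 80.3% of Gdf5 UMIs at E18.5. An osteoblast-like cluster with 72 of its 77 cells at E15.5 held 2.78% (2.18 to 3.49%) of that library. Its 10 leading genes hold 2 osteoblast and 2 hypertrophic markers, and in the E15.5 library clustered by itself a cluster of 76 cells with the same first 4 genes, Spp1, Mmp13, Ibsp and Col10a1, was named hypertrophic chondrocyte-like and no cluster osteoblast-like. No cluster was osteoblast-like at Leiden resolution 0.5 or with all deposited barcodes either, and the share was 1.24% by highest marker score. At E13.5 separate clustering gave 1.67% osteoblast-like cells, against 0.0711% with the libraries together. Connective tissue fibroblast-like cells held 0.640% (0.380 to 1.01%) at E13.5, 5.25% (4.42 to 6.18%) at E15.5 and 16.2% (14.6 to 17.9%) at E18.5, and 4.41% at E13.5 by highest marker score. With each library clustered by itself they held 11.2%, 0.782%, 7.33% and 16.8% in stage order, against 0% at E11.5 with the libraries together. Epithelium-like cells held 13.8% (12.5 to 15.2%), 8.64% (7.63 to 9.74%), 6.45% (5.53 to 7.46%) and 12.3% (10.8 to 13.8%) in stage order, the last 7.25% with the stricter filter on cells. Endothelium-like cells held 15.0% (13.6 to 16.4%) at E11.5 and 3.91%, 4.32% and 2.48% at the later stages. Macrophage-like and monocyte-like cells held 0.989%, 1.39%, 1.89% and 5.38%, but 2.17%, 3.86% and 8.18% at E11.5, E15.5 and E18.5 at Leiden resolution 0.5 and 0.586% at E13.5 without the 3% highest Scrublet scores. Melanocyte-like cells held 0.114%, 0.142%, 0.772% and 1.42%. Clusters that did not meet the naming rules stayed unnamed and held 1.18%, 25%, 16.3% and 6.12%. One of these, led by Dkk2, Chodl and Ogn, had 471 cells at E13.5 and 233 at E15.5. Another, led by the neutrophil gene Retnlg, had 51 cells, all at E18.5 (2.69% of that library), and stayed unnamed because 2 granulocyte markers and none of the macrophage list, which scored higher, were among its 10 leading genes. With 1 library per group, a cluster mostly of 1 library may be that library, not a type. Separate clustering also moved other classes: 21% of E11.5 cells fell in clusters named chondrocyte-like, muscle-like cells held 1.48% and epithelium-like cells 5.55% at E11.5, and all cartilage 35.6% at E15.5.

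**Figure D1:**
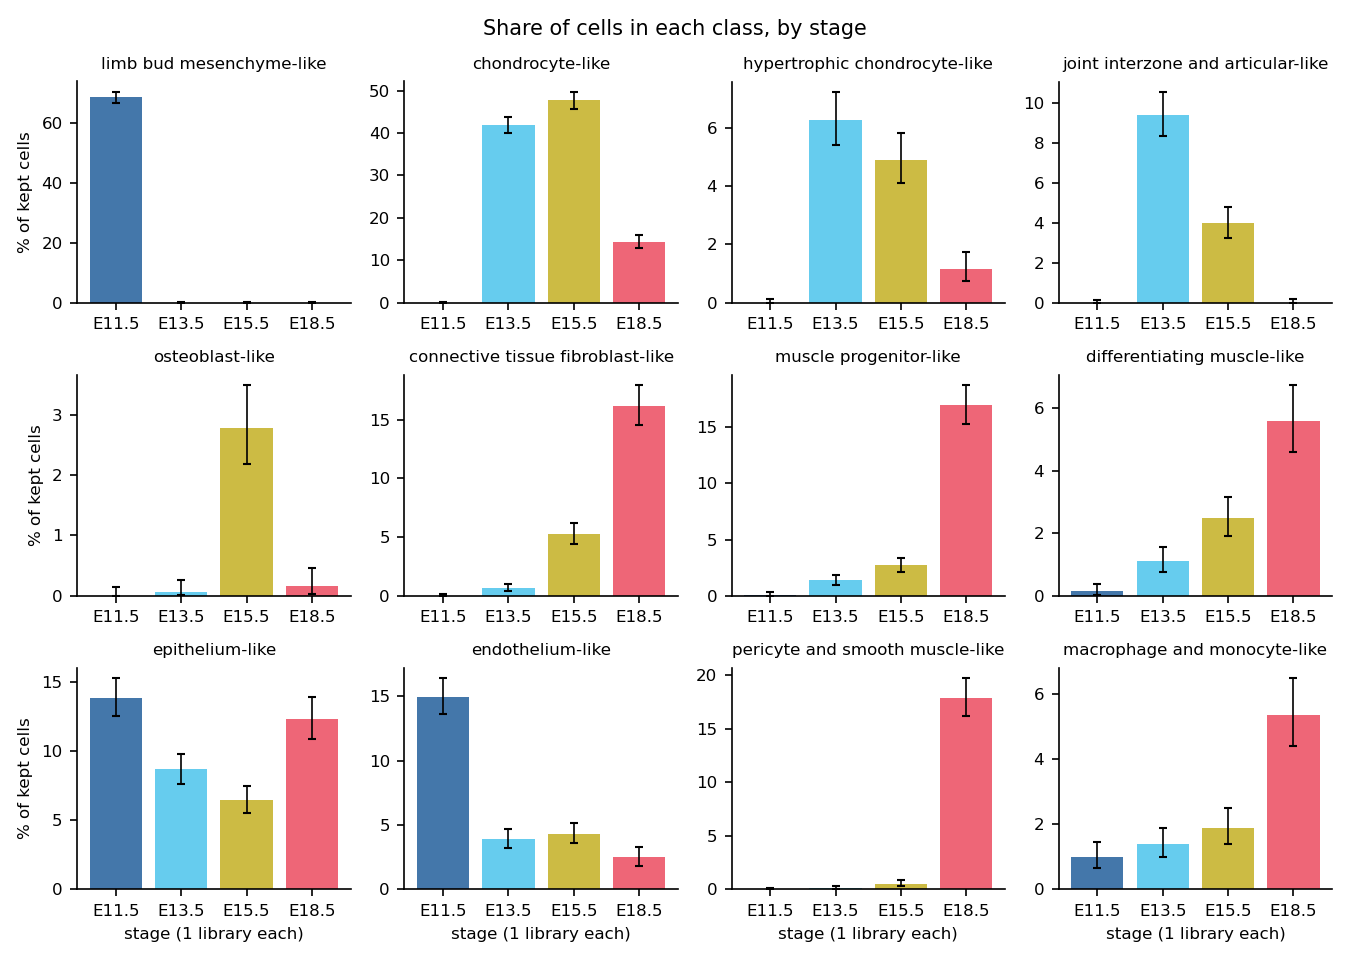
Share of kept cells (percent, bars) in each of 12 named cell classes at the 4 stages, 1 library per stage, with exact 95% intervals for counting error as error bars; the limb bud mesenchyme class includes cluster 2. Chondrocyte-like cells held 41.9% at E13.5, 47.7% at E15.5 and 14.4% at E18.5, while muscle progenitor-like cells stood at 16.9% (3.43% by highest marker score) and pericyte-like cells at 17.9% at E18.5.

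The comparison of E13.5 with E11.5 set the stage of cartilage condensation against the limb bud. Genes of cartilage matrix were higher at E13.5, and genes of limb bud patterning, early embryonic growth, simple epithelium and endothelium were lower. Acan (ENSMUSG00000030607, chromosome 7, 79053483 to 79115099, plus strand), which encodes the core protein of the proteoglycan aggrecan, was 968-fold higher (674 to 1445), from 29 to 25124 UMIs. Fgf8 (ENSMUSG00000025219, chromosome 19, 45736798 to 45742915, minus strand), the growth factor of the apical ectodermal ridge at the tip of the limb bud, was 86.4-fold lower (43.6 to 201), from 772 to 8 UMIs. By the size rule, 1945 of 15160 genes were higher and 3968 lower in counts-per-million (CPM, UMIs scaled to the library total). The median gene had a log2 ratio of -0.55, and relative to it 2958 genes were higher and 1457 lower. Every fold and list median is therefore given relative to the median gene of its own comparison, while counts of list members follow the rule in CPM.

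All 17 cartilage matrix genes were higher, with a median log2 ratio of 6.77 (6.50 to 7.05), at percentile 100 of 10000 random lists of genes of like level. Snorc, a membrane proteoglycan of cartilage listed as 3110079O15Rik, was 7702-fold higher (3909 to 17840), Epyc, a small proteoglycan, 2548-fold higher (1518 to 4660) and Matn1, a matrix adaptor protein, 893-fold higher (732 to 1101). Outside that list, Mia, a protein secreted by chondrocytes, was 3203-fold higher (1790 to 6417), Chad, a cell-binding matrix protein, 467-fold higher (254 to 974) and Mgp, an inhibitor of matrix calcification, 269-fold higher (209 to 352). Snorc and Mgp have short transcripts, and their log2 ratios of 12.91 and 8.07 were 10.86 and 6.02 when centred on genes of like transcript length. Of 10 chondrogenic regulators 6 were higher (median 1.80, 1.72 to 1.89), among them Fgfr3, a receptor that restrains chondrocyte proliferation, 21.1-fold higher (18.8 to 23.7) and Runx3 18.6-fold higher (14.5 to 24.1). Of 7 hypertrophy genes 5 were higher (median 2.79, 2.69 to 2.89). Col10a1 (ENSMUSG00000039462, chromosome 10, 34389981 to 34397085, plus strand), the collagen of hypertrophic cartilage, was 349.7-fold higher (177 to 811), Ihh, the hedgehog signal of prehypertrophic cells, 219-fold higher (134 to 383) and the channel gene Panx3 at least 946-fold higher, from 0 to 2542 UMIs. Osteoblast genes had 6 of 9 members higher (median 2.96, 2.74 to 3.17), with Ibsp, a mineral-binding protein, 51.9-fold higher (19.9 to 193) and Sp7, a transcription factor of bone formation, 16.7-fold higher (11.4 to 25.2). Joint genes had 3 higher and 3 lower of 10, or 5 and 2 relative to the median gene (median 1.11, 0.94 to 1.40, percentile 99.4 of the random lists): Barx1 was 13.8-fold higher, Nog, a BMP antagonist, 11.4-fold higher and Osr2 2.46-fold lower.

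Genes of the early limb bud were lower. Of 24 patterning genes 20 were lower (median -1.87, -1.97 to -1.74, percentile 0 of the random lists), among them the zinc finger genes Sall4, 22.7-fold lower (13.3 to 42.0), and Sall3, 18.8-fold lower (11.7 to 32.1), and the LIM homeobox gene Lhx9, 7.16-fold lower (6.4 to 8.02). All 6 hindlimb identity genes were lower, 5 of them relative to the median gene (median -1.27, -1.49 to -1.08), with Isl1, which acts upstream of hindlimb outgrowth, 4.04-fold lower (3.13 to 5.27), and Hoxc10 3.13-fold lower (2.92 to 3.35). Of 10 HoxA and HoxD genes 9 were lower (median -1.23, -1.32 to -1.16), led by Hoxd9, 3.94-fold lower (3.47 to 4.48). The early embryonic growth programme had 10 of 10 members lower (median -2.11, -2.25 to -1.98). Lin28b, which blocks maturation of let-7 microRNAs, was 19.1-fold lower (10.8 to 37.5), Trim71 15.3-fold lower (9.24 to 27.1) and the chromatin protein gene Hmga1 6.04-fold lower (5.71 to 6.38). Imprinted growth genes had 9 higher and 1 lower of 13, or 10 and 0 relative to the median gene (median 1.89, 1.78 to 2.0). The lower gene in CPM was Mest, and the higher ones included Dlk1, 24.6-fold higher (23.6 to 25.6), Meg3, 5.54-fold higher (5.46 to 5.62), and the cell cycle inhibitor gene Cdkn1c, 4.94-fold higher (4.88 to 5.0).

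Fibrous matrix genes had 14 of 20 higher (median 2.54, 2.40 to 2.68), with Ogn 56.7-fold higher and Lum 18.5-fold higher, both small leucine-rich proteoglycans. Tendon genes had 4 of 8 higher (median 2.26, 2.06 to 2.46), with Tnmd, a tendon membrane protein, 66.3-fold higher (28.1 to 206). Myogenic regulators had 7 higher and 1 lower of 12 (median 2.09, 1.63 to 2.53), and sarcomere genes 16 higher of 21 (median 2.07, 1.88 to 2.43). Myog (ENSMUSG00000026459, chromosome 1, 134289989 to 134292548, plus strand), the transcription factor of muscle differentiation, was 7.90-fold higher (7.01 to 8.93). Simple epithelial keratins had 3 of 4 lower (median -3.14, -3.27 to -3.01), with Krt8 41.0-fold lower (32.6 to 52.3) and its partner Krt18 11.3-fold lower (10.0 to 12.7). The epithelium-like cluster led by Krt8 had 124 cells at E11.5 and 5 at E13.5. Of 11 stratified epidermis genes 4 were higher (median 0.77, 0.53 to 0.97), with Krt15 13-fold higher (11.4 to 14.9). All 10 endothelium genes were lower (median -2.30, -2.38 to -2.24), with Plvap, a protein of vessel fenestrae, 7.71-fold lower (7.12 to 8.34), beside the endothelial share of 15.0% at E11.5 and 3.91% at E13.5. Pericyte and smooth muscle genes had 3 higher and 5 lower of 9, or 3 and 2 relative to the median gene (median -0.77, -0.88 to -0.61), with Cspg4 44.4-fold higher and Abcc9 5.55-fold lower. Neural crest and Schwann genes had 5 higher and 1 lower of 9 (median 1.65, 1.31 to 2.06), macrophage genes 2 and 1 of 10, or 3 and 1 relative to the median gene (median 0.54, 0.42 to 0.68), and 1 of 3 adipocyte genes, Fabp4, was higher. The pair of globin lists was not compared, since red cells are nearly missing: Hbb-y had 717 UMIs at E11.5, 599 of them in 1 cell, and 6 at E13.5.

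Of G2/M and S phase genes 8 of 18 and 10 of 18 were lower in CPM, and 1 and 3 relative to the median gene with medians of -0.38 (-0.46 to -0.32) and -0.60 (-0.63 to -0.52). Rrm2, a subunit of ribonucleotide reductase, was 2.25-fold lower (2.18 to 2.32) and Ccnb1, the mitotic cyclin, 2.0-fold lower (1.92 to 2.08). Cell cycle exit genes had 2 of 9 higher (median 0.73, 0.54 to 0.85), among them Cdkn2c, 7.79-fold higher (6.36 to 9.62). Immediate early and heat shock genes had 4 higher and 2 lower of 18, or 9 and 1 relative to the median gene (median 0.86, 0.80 to 0.92), with Fos 5.23-fold higher and Egr1 5.58-fold higher. Glycolysis and hypoxia genes had 4 higher and 2 lower of 19, or 4 and 0 relative to the median gene (median 0.32, 0.28 to 0.36), with Bnip3 5.59-fold higher and Pgk1 1.73-fold lower. Genes with a longest transcript under 1000 nt had a median log2 ratio of 1.41 in CPM and those of at least 1500 nt one of -0.66. With ratios centred on genes of like transcript length, the list medians were 2.02 for osteoblast, 1.64 for sarcomere, 0.12 for macrophage and -0.23 for the 13 mitochondrially encoded genes, whose median was 0.78 without centring.

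**Figure D2:**
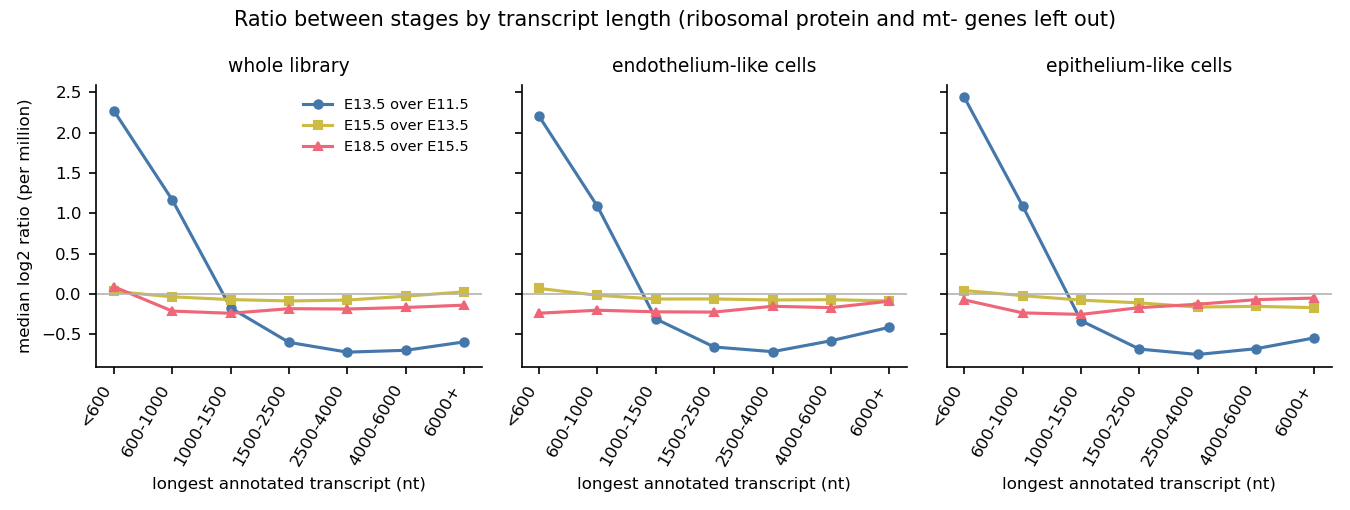
Median log2 ratio of CPM by bin of longest annotated transcript (nt), without ribosomal protein and mitochondrial genes, for the whole library and for endothelium-like and epithelium-like cells, 1 line per pair of successive stages. For E13.5 over E11.5 genes of under 1000 nt lay above genes of at least 1500 nt by 2.07 in the whole library, and for E15.5 over E13.5 by 0.03.

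The comparison of E15.5 with E13.5 set joint cavitation against cartilage condensation. Differences were fewer than for the earlier pair and lay mostly on the higher side, with 6 of 12 osteoblast genes and 6 of 12 myogenic regulators higher. Spp1 (ENSMUSG00000029304, chromosome 5, 104435118 to 104441050, plus strand), the mineral-binding matrix protein osteopontin, was 133-fold higher (118 to 150.1), from 274 to 30085 UMIs. Col10a1 was 7.85-fold higher (7.53 to 8.19), and the collagenase gene Mmp13 stood at 1 UMI at E13.5 and 2773 at E15.5, 3353-fold higher (601 to 132500). The osteoblast-like cluster of 72 cells held 95.7% of Spp1, 95.4% of Mmp13 and 79.7% of Col10a1 UMIs at E15.5. By the size rule 589 of 15263 genes were higher and 147 lower, with a median gene at -0.03.

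Of 12 osteoblast genes 6 were higher (median 0.72, 0.35 to 0.99, percentile 100 of the random lists), including Dmp1, a mineralisation protein, 37.8-fold higher (14.4 to 141), and Ibsp 15.8-fold higher (13.7 to 18.5). Hypertrophy genes had 2 of 8 higher (median 0.12, 0.08 to 0.16), Col10a1 and Mmp13. Cartilage matrix genes had 1 of 17 higher (median 0.30, 0.28 to 0.31), Ucma (ENSMUSG00000026668, chromosome 2, 4976122 to 4985748, plus strand), a matrix protein of upper zone cartilage, at 2.39-fold higher (2.11 to 2.71). Col2a1 (ENSMUSG00000022483, chromosome 15, 97975602 to 98004695, minus strand), the main collagen of cartilage, was 1.39-fold higher (1.38 to 1.40), below the limit of the rule. Joint genes had 1 of 10 lower (median -0.32, -0.44 to -0.17): Sfrp2, a secreted WNT modulator, was 2.50-fold lower (2.35 to 2.66), and Gdf5 was 1.36-fold lower (1.22 to 1.52), within the limit of the rule. Tendon genes had 1 of 8 lower (median -0.35, -0.56 to -0.24), the transcription factor gene Scx at 2.01-fold lower (1.75 to 2.31). Fibrous matrix genes had 2 of 20 higher (median 0.73, 0.68 to 0.77), among them the proteoglycan gene Dcn, 3.37-fold higher (3.22 to 3.52). Myogenic regulators had 6 of 12 higher (median 1.21, 1.03 to 1.44) and sarcomere genes 5 of 22 (median 0.59, 0.54 to 0.69). Myog was 2.93-fold higher (2.79 to 3.08), Pax7, the gene of muscle stem cells, 2.87-fold higher (1.91 to 4.39) and cardiac actin, Actc1, 2.88-fold higher (2.75 to 3.01), beside a muscle-like share of 2.49% at E13.5 and 5.17% at E15.5.

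Stratified epidermis genes had 4 of 12 higher (median 0.44, 0.36 to 0.52), with Krtdap 4.24-fold higher and Krt1 3.66-fold higher, both made by keratinocytes that have left the basal layer. Of the 4 simple epithelial keratins 1 was higher, Krt8 (median 0.30, 0.17 to 0.46, but -0.08 with the stricter filter on cells). Macrophage genes had 3 of 10 higher (median 0.85, 0.71 to 0.99), with the complement gene C1qa 6.95-fold higher (5.49 to 8.88) and the mannose receptor gene Mrc1 9.27-fold higher (5.39 to 17.1). Pericyte and smooth muscle genes had 3 of 10 higher (median 0.83, 0.54 to 1.12), with Rgs5 4.13-fold higher (3.18 to 5.43). Among the 10 highest ratios were those of single genes known from white blood cells and lymphatic vessels: Cma1, a protease of mast cells, was 21.5-fold higher (18.7 to 24.8), S100a8, a calcium-binding protein of neutrophils, 12.1-fold higher (10.9 to 13.5) and Ccl21a, a chemokine of lymphatic endothelium, 18-fold higher (16.1 to 20.2). Neural crest and adipocyte genes had 1 of 9 and 1 of 3 higher. The lists of limb bud patterning, hindlimb identity, HoxA and HoxD, early growth, chondrogenic regulators, both cell cycle lists, cell cycle exit, imprinted growth, immediate early, glycolysis, endothelium and mitochondrially encoded genes had no member past the rule. Their medians lay between -0.27, for S phase, and 0.47, for cell cycle exit. Among single genes Hmga2, 1.73-fold lower (1.65 to 1.81), and the histone gene Hist1h2ap, 1.85-fold lower (1.81 to 1.89), had ratios among the 10 lowest.

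The comparison of E18.5 with E15.5 set joint morphogenesis against joint cavitation. Genes of the pericyte, fibrous matrix, stratified epidermis, adipocyte and macrophage lists were higher at E18.5, and genes of cartilage and hypertrophy were lower. Rgs5 (ENSMUSG00000026678, chromosome 1, 169655501 to 169695813, plus strand), a regulator of G protein signalling used as a pericyte marker, was 55.2-fold higher (48.7 to 62.8), from 253 to 6258 UMIs. Col3a1 (ENSMUSG00000026043, chromosome 1, 45311538 to 45349706, plus strand), a fibrillar collagen of connective tissue, was 6.93-fold higher (6.78 to 7.09). Col10a1 was 19.7-fold lower (17.8 to 21.9) and Acan 3.56-fold lower (3.44 to 3.70). By the size rule 1743 of 14930 genes were higher and 1225 lower, with a median gene at -0.14; relative to it the counts were 2044 and 944.

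Cartilage matrix genes had 14 lower and 1 higher of 17 (median -1.40, -1.48 to -1.33, percentile 0 of the random lists), beside an all-cartilage share of 52.6% at E15.5 and 15.6% at E18.5. The higher gene was Ucma, 15.6-fold higher (14.5 to 16.8), whereas Matn4 was 4.58-fold lower (4.38 to 4.79). Within chondrocyte-like cluster 16 alone the list went the other way, with 7 of 17 higher and 0 lower (median 0.75). Chondrogenic regulators had 7 of 11 lower (median -1.39, -1.56 to -1.20; 1 higher and 7 lower relative to the median gene), with Sox5 4.92-fold lower (4.38 to 5.54). Hypertrophy genes had 5 of 8 lower (median -1.24, -1.33 to -1.17), with Mmp13 8.81-fold lower (7.44 to 10.5) and Panx3 8.02-fold lower (6.58 to 9.88). Osteoblast genes had 6 lower and 2 higher of 13, or 6 and 3 relative to the median gene (median -0.85, -1.33 to -0.64): Ibsp was 11-fold lower (9.03 to 13.6) and Spp1 4.53-fold lower (4.37 to 4.71), while osteocalcin, Bglap, was 12.9-fold higher (7.89 to 22.3). At E18.5 3 cells of the osteoblast-like cluster held 68.7% of Spp1 and 87.9% of Mmp13 UMIs, so the ratios of these 2 genes rest on few cells. Joint genes had 1 higher and 3 lower of 9, or 2 and 3 relative to the median gene (median -0.18, -0.34 to -0.04). Prg4 (ENSMUSG00000006014, chromosome 1, 150449412 to 150466165, minus strand), which encodes the joint lubricant lubricin, was 24.7-fold higher (14.6 to 45.1), from 15 to 166 UMIs, and Gdf5 was 3.24-fold lower (2.55 to 4.18). Of the limb bud lists, patterning genes had 3 higher and 3 lower of 21, hindlimb identity genes 1 and 3 of 6 with Pitx1 3.44-fold lower (3.02 to 3.93), and HoxA and HoxD genes 3 lower of 10 with Hoxd12 7.42-fold lower (4.49 to 13.2). Early growth genes had 2 of 8 lower, with Hmga2 6.30-fold lower (5.41 to 7.37).

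Fibrous matrix genes had 17 of 20 higher (median 1.92, 1.84 to 2.03), including Col1a1, 6.19-fold higher (6.05 to 6.33), and Postn, 6.09-fold higher (5.70 to 6.52). Tendon genes had 3 higher and 1 lower of 8 (median 0.92, 0.77 to 1.09). Pericyte and smooth muscle genes had 9 higher and 1 lower of 10 in CPM, or 9 and 0 relative to the median gene (median 4.02, 3.95 to 4.12, percentile 100 of the random lists), with the channel genes Abcc9 and Kcnj8 73.2-fold higher and 32.7-fold higher. All 5 adipocyte genes were higher (median 4.16, 2.90 to 4.46), with Adipoq, the fat cell hormone adiponectin, 109-fold higher (29.5 to 916), from 2 to 98 UMIs, and the fatty acid carrier gene Fabp4 19.4-fold higher (16.8 to 22.4). Myogenic regulators had 6 of 12 higher (median 1.09, 0.85 to 1.32), with Myf5 4.87-fold higher (3.85 to 6.19). Sarcomere genes had 4 higher and 3 lower of 22 (median 0.31, 0.18 to 0.47, but -0.09 with the stricter filter on cells), with skeletal actin, Acta1, 4.91-fold higher (4.29 to 5.62). Slow troponin C, Tnnc1, was 3.55-fold lower (2.62 to 4.90), a log2 ratio of -1.83 that was -0.92 as a mean over cells. Stratified epidermis genes had 11 higher and 1 lower of 13 (median 2.09, 2.02 to 2.33). Krt5 (ENSMUSG00000061527, chromosome 15, 101707070 to 101712898, minus strand) and Krt14, the keratin pair of basal epidermis, were 8.26-fold higher (7.88 to 8.66) and 7.47-fold higher (7.24 to 7.71), and the simple keratin Krt19 was 9.33-fold lower (6.39 to 14.2). Macrophage genes had 8 of 10 higher (median 1.84, 1.75 to 1.93), with lysozyme, Lyz2, 7.76-fold higher (7.46 to 8.07). Endothelium genes had 2 higher and 3 lower of 10, or 2 and 2 relative to the median gene, and neural crest genes 1 lower of 9, or 1 higher and 1 lower relative to the median gene.

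Among the 10 highest ratios were those of single genes known from neutrophils and of chemokine genes. Retnlg, a secreted protein of neutrophils, was 8325-fold higher (2304 to 68760), from 2 to 7461 UMIs, and Stfa2, a protease inhibitor, 856-fold higher (415 to 2132); a cluster of 51 cells held 91.8% and 92.0% of their UMIs. The chemokine genes Cxcl1, Ccl2 and Cxcl2 were 129-fold higher (105 to 161), 91.0-fold higher (72.7 to 116) and 54.1-fold higher (47.3 to 62.0), and the pericyte-like cluster, in whose leading genes Cxcl1 and Ccl2 stand beside Rgs5, held 87.0% of Cxcl1 UMIs at E18.5. Immediate early and heat shock genes, which are also sensitive to cell handling, had 7 higher and 1 lower of 18 (median 1.04, 0.98 to 1.09), with Hspa1a 21.5-fold higher (20.1 to 22.9). G2/M genes had 6 of 18 lower in CPM and 3 relative to the median gene (median -0.67, -0.73 to -0.60), S phase genes none (median 0.07, -0.02 to 0.11), and cell cycle exit genes 0 and 3 higher (median 0.76, 0.73 to 0.89). Imprinted growth genes had 1 lower of 13, Igf2, 1.95-fold lower (1.90 to 2.01), and 0 relative to the median gene (median -0.46, -0.52 to -0.39), and glycolysis genes 3 higher and 1 lower of 19, or 3 and 0 (median 0.17, 0.12 to 0.23).

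**Figure D3:**
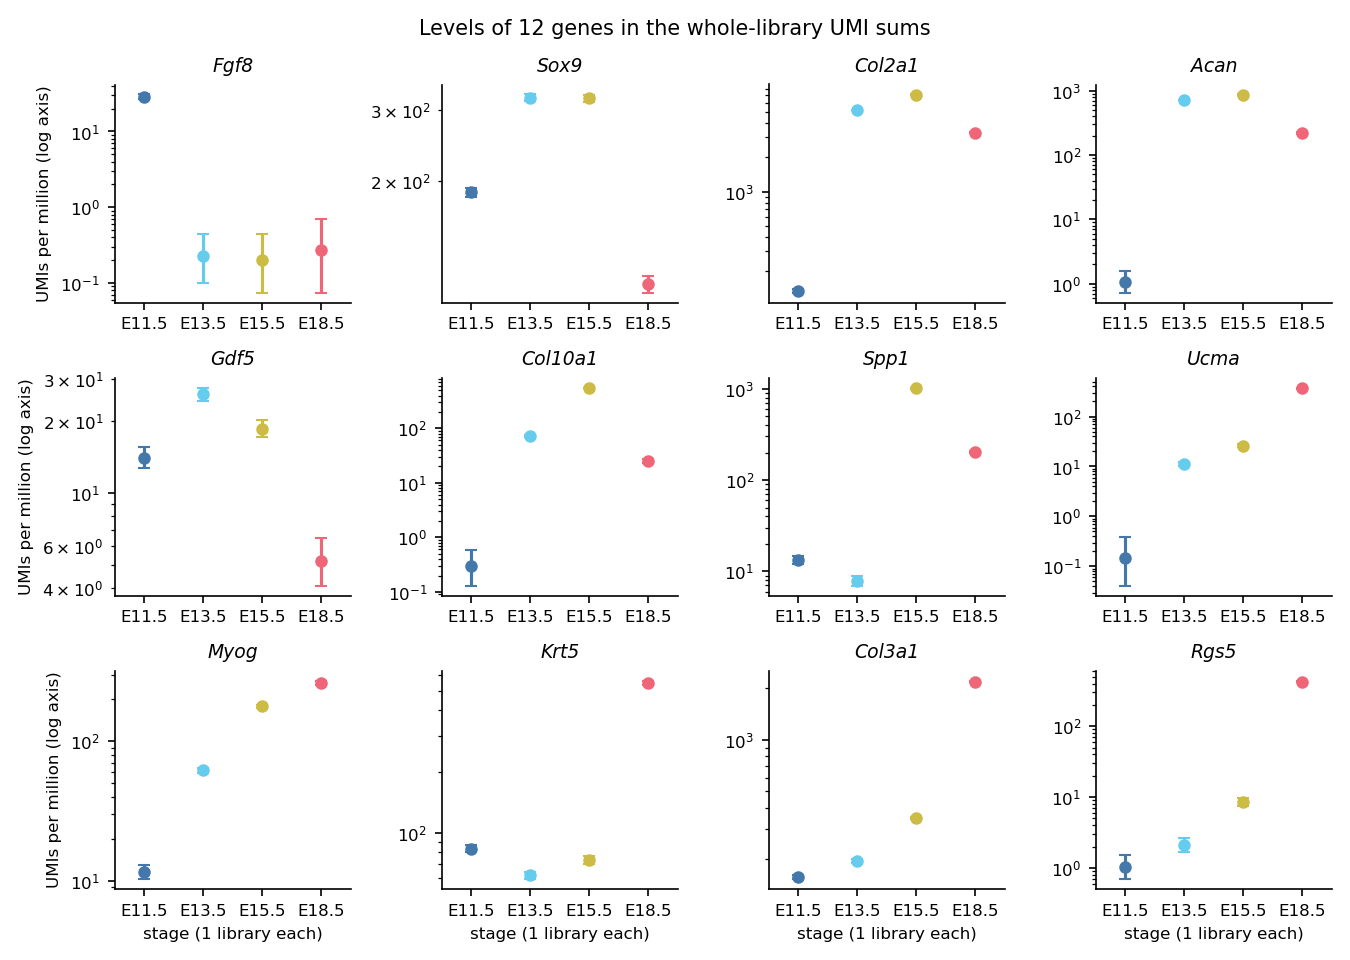
Level of 12 named genes (CPM in the whole library, log axis) at the 4 stages, 1 library per stage, with exact Poisson 95% intervals as error bars. Acan stood at 1.08 CPM at E11.5 and 716 at E13.5, and Rgs5 at 8.54 at E15.5 and 427 at E18.5.

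Over the whole span, E18.5 against E11.5, cartilage matrix, pericyte, fibrous matrix and macrophage genes were higher and the limb bud programme was lower. The size rule counted 2450 genes higher and 5186 lower of 14872, with a median gene at -0.63, and 3637 and 2067 relative to it. All 17 cartilage matrix genes were higher (median 5.65, 5.53 to 5.83), as were all 10 pericyte genes (median 4.75, 4.56 to 4.97), 19 of 20 fibrous matrix genes (median 4.53, 4.47 to 4.62) and 9 of 10 macrophage genes (median 3.67, 3.53 to 3.82). Rgs5 was 633-fold higher (437 to 953), Ucma 3823-fold higher (1492 to 14040) (log2 11.90, or 9.84 centred on transcript length) and Pax7 at least 106-fold higher, from 0 to 112 UMIs. Patterning genes had 1 higher and 19 lower of 24 (median -1.89, -2.12 to -1.58), early growth genes 10 lower of 10 (median -2.69, -2.88 to -2.45) and endothelium genes 10 of 10 (median -1.91, -2.14 to -1.71). Hmga2 was 33.1-fold lower (28.6 to 38.5), Fgf8 68.2-fold lower (26.5 to 251) and Sall4 at least 41.8-fold lower. G2/M and S phase genes had 16 and 17 of 18 each lower in CPM, and 8 and 7 relative to the median gene.

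**Figure D4:**
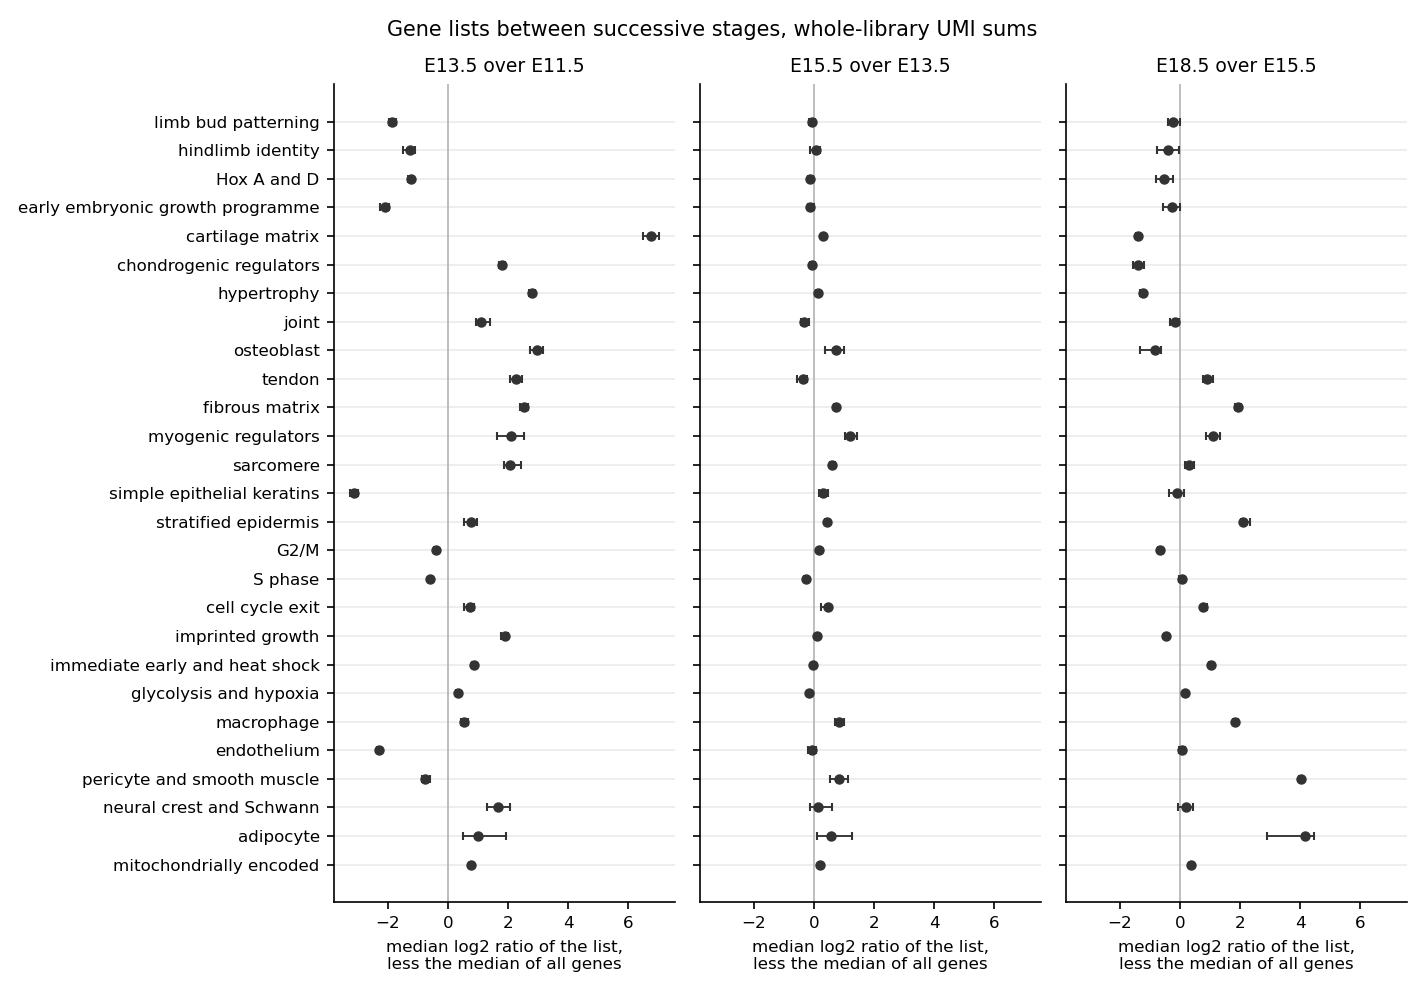
Median log2 ratio of 27 gene lists, relative to the median gene, for the 3 pairs of successive stages, with counting intervals as error bars. The cartilage matrix list lies at 6.77 for E13.5 over E11.5, 0.30 for E15.5 over E13.5 and -1.40 for E18.5 over E15.5, and the pericyte list at -0.77, 0.83 and 4.02.

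Within chondrocyte-like cells, E15.5 was close to E13.5 and at E18.5 genes of fibrous matrix and tendon were higher, and 4 of 8 joint genes through a cluster that E15.5 nearly lacked. At E15.5 over E13.5 231 genes were higher and 91 lower, with Dcn 3.79-fold higher (3.4 to 4.23) and Fmod, a collagen-binding proteoglycan, 2.60-fold higher (2.43 to 2.80), and an S phase median of -0.39 (-0.43 to -0.34). Spp1 was 48.5-fold higher (28.1 to 91.6), but its level of 35.5 CPM at E15.5 was like the 36.4 CPM in endothelium-like and 32.1 CPM in muscle progenitor-like cells, and is read here as free RNA. The largest part of the class was cluster 17 at E13.5 (38.9%) and cluster 16 at E15.5 (49.0%). Within cluster 16 alone 100 genes were higher and 97 lower in this pair. Dcn had a log2 ratio of 1.82 there and Fmod one of 0.91, and the S phase median was -0.23. At E18.5 over E15.5 785 genes of the whole class were higher and 401 lower. Fibrous matrix genes had 16 of 20 higher (median 2.73, 2.52 to 2.93), with Ogn 16.1-fold higher (11.7 to 22.3) and Bgn 12.9-fold higher (12.3 to 13.4), and tendon genes all 6 (median 2.84, 2.26 to 3.13). Joint genes had 4 of 8 higher (median 1.09, 0.74 to 1.40), with Prg4 at 4 and 152 UMIs, 295-fold higher (113 to 1098), and Gdf5 3.92-fold higher (2.87 to 5.30). By highest marker score the joint median was 0.17. Ucma was 54.9-fold higher (50.8 to 59.4), and HoxA and HoxD genes had 6 of 10 higher (median 1.07, 0.79 to 1.15). Hypertrophy genes had 4 lower and 1 higher of 8 (median -1.05, -1.23 to -0.37), with Col10a1 8.11-fold lower (3.69 to 22.2). The osteoblast-like cluster, with 72 cells at E15.5 and 3 at E18.5, held 79.7% of all Col10a1 UMIs at E15.5. Free RNA from that cluster was not told apart from Col10a1 expression in chondrocyte-like cells. Early growth genes had 3 lower and 1 higher of 7 with Hmga2 6.88-fold lower (4.77 to 10.3), and G2/M genes 6 lower of 18 (median -0.71, -0.89 to -0.64). Stress genes had 12 of 18 higher (median 1.19, 1.11 to 1.25), with Hspa1a 63.2-fold higher (57.5 to 69.6). Cluster 16 held 49.0% of chondrocyte-like cells at E15.5 and cluster 26, whose leading genes include Ucma, Fmod and the heat shock genes Hspa1a and Hspa1b, 75.1% at E18.5. Within cluster 16 alone, with 31 cells at E18.5, the medians were 0.47 for fibrous matrix, 0.00 for tendon, -0.38 for joint, 0.64 for G2/M and -0.22 for stress genes, with Ucma at a log2 ratio of 3.78 against 5.78 in the class. With cluster 26 alone left out, which leaves 68 cells at E18.5, the medians in the same order were 1.18, 1.06, -1.33, -0.13 and 0.16, and Ucma stood at 3.44. HoxA and HoxD genes had 1 of 9 higher in cluster 16 alone (median 0.64) and 3 of 10 without cluster 26 (0.54). Hypertrophy genes had 2 of 8 lower in the former (median -0.51) and 2 lower and 1 higher in the latter (-0.38), and a median of -0.18 by highest marker score. Cartilage matrix genes, lower in the whole library, were not lower here. In cluster 16 alone 7 of 17 were higher and 0 lower (median 0.75), and without cluster 26 3 were higher and 0 lower (0.57). In the class Col2a1 stood at 11100 CPM at E15.5 and 20940 at E18.5, Col9a1 at 3509 and 5830, and Acan at 1353 and 1306.

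Within hypertrophic chondrocyte-like cells at E15.5 over E13.5, Col10a1 was 2.54-fold higher (2.40 to 2.69), Fn1, the matrix protein fibronectin, 2.68-fold higher (2.45 to 2.94) and Wif1, a WNT inhibitor, 2.84-fold higher (2.35 to 3.44). The log2 ratio of Wif1, 1.51, was 0.67 by highest marker score, 0.77 with each library clustered by itself and 0.68 with all deposited barcodes. Of 18 S phase genes 7 were lower (median -0.81, -0.97 to -0.66), Mcm3, a DNA helicase subunit, at 2.72-fold lower (1.95 to 3.89). Within joint-like cells over the same stages, the proteoglycan gene Lum was 3.08-fold higher (2.24 to 4.22) and Fbln5, an elastic fibre protein, 2.55-fold higher (1.84 to 3.53), while Ndufa4l2 was 6.66-fold lower (4.10 to 11.6). The log2 ratio of Fbln5, 1.35, was 0.55 by highest marker score and 0.66 with the Scrublet calls kept. Gdf5 was 1.5-fold higher (1.29 to 1.75) and Sfrp2 1.52-fold lower (1.33 to 1.74), neither past the rule, and G2/M genes had a median of -0.76 (-1.16 to -0.26). At Leiden resolution 0.5 both turned, with a log2 ratio of -0.13 for Gdf5 and a G2/M median of 0.23. By the rule 218 and 144 genes were higher and lower in the hypertrophic class, and 114 and 128 in the joint class, or 137 and 119 relative to its median gene.

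Within connective tissue fibroblast-like cells at E18.5 over E15.5, genes of the fibrous matrix and adipocyte lists were higher and dividing cell genes were lower. Pericyte genes also had higher ratios, but free RNA was not told apart from expression for them. Postn was 15.9-fold higher (12.1 to 21.4), Fabp4 at least 124-fold higher, from 0 to 581 UMIs, and all 5 adipocyte genes were higher (median 3.23, 2.77 to 3.59). Fibrous matrix genes had 13 of 19 higher (median 1.41, 1.31 to 1.57) and imprinted growth genes 4 of 13 (median 0.87, 0.79 to 1.05), with Dlk1 4.94-fold higher (4.62 to 5.29). Cluster 27, led by Mfap5, Tnxb and Clec3b with Postn and Ogn among its 10 leading genes, held 91 of the 307 cells at E18.5 and 2 of 136 at E15.5. Within the other cluster, 15, the medians were 1.55 for fibrous matrix, -0.55 for G2/M and 0.17 for imprinted growth, with Postn at a log2 ratio of 3.73, Fabp4, with 0 and 113 UMIs, at 5.24 or more and Dlk1 at 1.08. Mest, 2.57-fold higher (2.29 to 2.88) in the class, was lower in cluster 15, with a log2 ratio of -1.09, and at Leiden resolution 0.5, with -1.07. Pericyte and smooth muscle genes had 5 higher and 1 lower of 8 (median 2.23, 1.61 to 3.21), with Rgs5 32.8-fold higher (8.86 to 275), Tagln 15.5-fold higher (5.85 to 57.9) and Acta2 10.4-fold higher (6.09 to 19.4), and in cluster 15 alone 4 and 1 of 6 (median 1.97). In the whole class Rgs5 stood at 50.2 CPM at E18.5, beside 13.2 CPM in chondrocyte-like, 15.1 CPM in epithelium-like, 20.6 CPM in endothelium-like and 2151 CPM in pericyte-like cells. Cluster 15 held 24 of the 103 Rgs5 UMIs of the class at E18.5, and 2 UMIs at E15.5. Crabp1, a retinoic acid carrier, was 5.38-fold lower (4.99 to 5.80), the protease gene Mmp11 8.03-fold lower (6.42 to 10.1) and Wnt4 5.24-fold lower (3.67 to 7.62). G2/M genes had 11 of 18 lower (median -0.99, -1.15 to -0.84). Counts by the rule were 678 higher and 733 lower, or 875 and 414 relative to a median gene at -0.20. Stress genes had 10 of 18 higher (median 1.30, 1.18 to 1.53), and the chemokine gene Ccl2 stood at 1 and 293 UMIs, 187-fold higher (33.3 to 7405).

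Within muscle progenitor-like cells, 4 of 8 cell cycle exit genes were higher and 8 of 18 G2/M genes lower at E18.5 than at E15.5. At E15.5 over E13.5 Dlk1 was 6.4-fold higher (5.32 to 7.76) and Hmga2 4.07-fold lower (2.77 to 6.09). At E18.5 over E15.5 cell cycle exit genes had a median of 1.13 (0.81 to 1.54), with the inhibitor gene Cdkn1a 5.33-fold higher (3.55 to 8.32), and G2/M genes one of -0.79 (-0.96 to -0.58), with Ccnb1 3.77-fold lower (2.98 to 4.78). Col15a1, a basement membrane collagen, was 14.4-fold higher (9.22 to 23.8), Dlk1 3.43-fold higher (3.25 to 3.63) and Crabp2 8.18-fold lower (5.92 to 11.5), while myogenic regulators had 1 higher and 1 lower of 10, or 1 and 0 relative to the median gene (median -0.25, -0.43 to 0.03). Stress genes had 8 of 18 higher (median 1.15, 0.92 to 1.28). Within differentiating muscle-like cells, sarcomere genes were 0 higher and 5 lower of 21 at E15.5 over E13.5, or 1 and 4 relative to the median gene (median -0.50, -0.59 to -0.38, but 0.49 with each library clustered by itself), and 2 and 7 of 21 at E18.5 over E15.5 (median -0.42, -0.56 to -0.33). Tnnc1 was 3.49-fold lower (3.02 to 4.03) and then 14.5-fold lower (8.63 to 26.2). Its log2 ratio of -1.80 in the earlier pair was -0.61 with each library clustered by itself. Myh3, the embryonic myosin heavy chain, was 5.94-fold lower (3.76 to 9.85) in the later pair. The median gene lay at -0.18 in progenitors and -0.25 in differentiating cells at E18.5 over E15.5, and the counts were 476 higher and 617 lower (653 and 382 relative to it), and 190 and 611 (330 and 358).

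Within epithelium-like cells the keratins differed at each step. At E13.5 over E11.5 Fgf8 was at least 135-fold lower, from 744 to 0 UMIs, Krt8 49.8-fold lower (35.7 to 71.6) and Krt18 21.5-fold lower (17.3 to 27.0). Cluster 5, with Krt8, Krt19, Krt18 and Krt7 among its leading genes, had 124 cells at E11.5 and 5 at E13.5. The Krt8 and Krt18 ratios therefore compare unlike mixes of epithelium-like cells. Krt15 was 21.9-fold higher (19.1 to 25.3) and Krt10 18.2-fold higher (12.6 to 27.0), with 6 of 11 stratified genes higher (median 2.65, 1.76 to 3.16). At E15.5 over E13.5 Krt4, a keratin of internal and embryonic surface epithelia, was 19.9-fold higher (16.3 to 24.4) and 7 of 12 stratified genes were higher (median 1.51, 1.17 to 1.58). At E18.5 over E15.5 Krt79 and Krt42 were at least 514-fold higher and at least 345-fold higher, Krt10 5.50-fold higher (5.03 to 6.02) and Krt14 4.18-fold higher (4.05 to 4.32), and Krt4 was at least 339-fold lower, from 1255 to 0 UMIs. Both Krt4 ratios rest on few cells, since 85.8% of its UMIs at E15.5 lay in 7 cells of cluster 5, which had 0 cells at E18.5. Stratified genes had 9 higher and 1 lower of 13, the lower gene being loricrin, Lor, 5.33-fold lower (3.19 to 9.48), and imprinted growth genes 6 lower of 12 (median -0.84, -1.09 to -0.55). In the same cells 15 of 16 cartilage matrix genes were lower (median -2.80, -3.01 to -2.42, or -1.49 with the 3% highest Scrublet scores left out). The median gene lay at -0.58, -0.14 and -0.16 for the 3 pairs. Cluster 6 held 65.4% of the class at E11.5, cluster 11 91.0% and 68.9% at E13.5 and E15.5, and cluster 24 99.6% at E18.5. Within cluster 24 alone at E18.5 over E15.5 the medians were 0.38 for stratified epidermis, -1.70 for imprinted growth and -4.30 for cartilage matrix, and Krt10 had a log2 ratio of 0.63. Within cluster 11 alone at E15.5 over E13.5 the stratified median was 0.58, and with the stricter filter on cells that of the class was 0.85.

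Within endothelium-like cells, 7 of 9 early growth genes were lower at E13.5 than at E11.5 (median -1.06, -1.33 to -0.69). Glycolysis genes had 10 of 18 lower in CPM, but 3 lower and 1 higher relative to the median gene (median -0.63, -0.74 to -0.48), which lay at -0.51. Hmga1 was 5.68-fold lower (4.13 to 8.03) and Pgk1, a glycolytic kinase, 4.71-fold lower (3.56 to 6.35). These compare different clusters, 3 with 98.2% of the class at E11.5 and 4 with 92.7% at E13.5. The lymphatic genes Ccl21a and Lyve1 were 15.5-fold higher (13.8 to 17.4) and 11.4-fold higher (6.16 to 23.4) at E15.5 over E13.5, and the glucose carrier gene Slc2a1 2.58-fold lower (1.90 to 3.55). Cluster 10, with Ccl21a and Lyve1 among its leading genes, had 6 cells at E13.5 and 40 at E15.5. It held 95.25% and 97.95% of the Ccl21a UMIs of these libraries, so the Ccl21a ratio compares unlike mixes of cells. At E18.5 over E15.5 G2/M genes had 13 of 18 lower (median -1.76, -2.12 to -1.38) and S phase genes 11 of 17 (median -1.46, -1.83 to -0.99), in 47 cells at E18.5, most of them in the lymphatic cluster 10 (55.3%) against cluster 4 at E15.5 (62.5%). Within macrophage-like cells C1qa was 6.97-fold higher (5.49 to 8.95) at E15.5 over E13.5, beside the neutrophil gene S100a8, 180.5-fold higher (112 to 310.4), whose UMIs came from 8.16% of the 49 cells at E15.5 and 2.56% of 39 at E13.5. At E18.5 over E15.5 the microglial and resident macrophage receptor gene Cx3cr1 was 6.76-fold lower (4.48 to 10.6), Lyz2 2.78-fold higher (2.67 to 2.90), and G2/M genes had 14 of 18 lower (median -1.16, -1.44 to -0.96), with stress genes 5 of 18 higher (median 0.94, 0.78 to 1.09). Counts were 297 higher and 725 lower, or 489 and 390 relative to a median gene at -0.26. Cartilage matrix genes had UMIs in classes that are not known to make them, and their ratios are not read here as expression of these classes. In endothelium-like cells their median was 7.28 (6.92 to 7.48) at E13.5 over E11.5 and -4.17 (-4.34 to -3.50) at E18.5 over E15.5, the latter -1.76 with the 3% highest Scrublet scores left out. In epithelium-like cells these medians were 6.18 and -2.80, and in macrophage-like cells 14 of 14 were lower at E18.5 over E15.5 (median -2.74, or -1.77 without those scores). At E15.5 over E13.5 3 of 16 were higher in endothelium-like and 0 of 16 in epithelium-like cells, but 15 were lower in cluster 11 alone.

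The last comparison asked how many cells carried lineage genes at an equal total of 2000 UMIs per cell; no kept cell was shallower. Ribosomal protein genes took 10.9% of UMIs at E11.5 and 26.8%, 27.9% and 27.9% later, so the other genes together were sampled more deeply at E11.5 than at the later stages. Sox9, the master regulator of cartilage, had a UMI in 28.0% (26.3 to 29.8%) of cells at E11.5, 40.8% (39.0 to 42.6%) at E13.5, 40.1% (38.2 to 42.0%) at E15.5 and 15.7% (14.1 to 17.4%) at E18.5, and in 1.78%, 3.64%, 3.57% and 0% of endothelium-like cells, taken as background. Without thinning the shares were 57.5%, 73.3%, 69.0% and 29.9%; median depths were those above, and 10920, 9452, 9020 and 5736 UMIs in endothelium-like cells. Prrx1, a gene of limb mesenchyme, had a UMI in 34.2% (32.4 to 36.0%) at E11.5 and 10.9% (9.75 to 12.1%) at E13.5 (unthinned 56.4% and 26.0%), against 0.761% and 0% of endothelium-like cells. Col2a1 had one in 77.3% (75.7 to 78.8%) at E13.5 (unthinned 95.3%), but also in 41.8% of endothelium-like cells. Scx had one in 6.88% (5.94 to 7.92%) at E11.5 and 1.66% (1.20 to 2.23%) at E15.5 (unthinned 20.6% and 5.13%), with 0.254% and 0.893% of endothelium-like cells, and Top2a, a gene of dividing cells, in 38.9% (37.0 to 40.8%) at E11.5 and 16.4% (14.7 to 18.1%) at E18.5 (unthinned 64.9% and 31.9%; endothelium-like cells 32.0% and 8.51%). The ratio of cells with both Sox9 and Scx, the pair of genes of tendon-to-bone attachment progenitors, to the number that independence within the library gives was 1.54 at E11.5 (1.22 to 1.91), 0.689 at E13.5 (0.478 to 0.960), 0.754 at E15.5 (0.402 to 1.29) and 0.530 at E18.5 (0.0642 to 1.91), the last from 2 cells. For Sox9 and Gdf5 it was 1.61 at E11.5 (1.16 to 2.17), 1.49 at E13.5 (1.20 to 1.83), 1.62 at E15.5 (1.24 to 2.09) and 3.18 at E18.5 (1.38 to 6.25), and for Sox9 and Runx2 1.73 at E11.5 (1.01 to 2.77), 1.10 at E13.5 (0.835 to 1.43), 1.25 at E15.5 (0.993 to 1.56) and 2.83 at E18.5 (1.22 to 5.56), with 8 cells behind either E18.5 value. Endothelium-like cells had 0% with Gdf5 and 0% with Runx2 at each stage, with exact upper limits of 0.932%, 3.30%, 3.24% and 7.55%. The expected numbers were taken over all cells of a library. Genes confined to the same part of its cells therefore give a ratio above 1 even where they are independent within that part. At E11.5 limb bud mesenchyme-like cells held 97.5% of Scx and 98.9% of Gdf5 UMIs. A ratio above 1 thus cannot show that these genes go together within a class.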

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

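The differences in this part are between classes whose list medians lay on opposite sides of 0 by at least 0.5 over at least 5 members at the same pair of stages. These limits were chosen after the data were seen, and none of the differences was tested.

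Imprinted growth genes, which are expressed from the copy of 1 parent and set the pace of fetal growth, had list medians on opposite sides of 0 in connective tissue and in surface epithelium at E18.5 over E15.5, with fewer than all members past the size rule in either. In connective tissue fibroblast-like cells 4 of 13 members were higher (median log2 ratio 0.87, 0.79 to 1.05), with the transcription factor gene Plagl1 5.30-fold higher (3.92 to 7.31), Dlk1 4.94-fold higher and the noncoding gene H19 3.12-fold higher (2.90 to 3.37), a log2 ratio of 1.64 that was 0.80 in cluster 15 alone, 0.79 at Leiden resolution 0.5 and 0.84 by highest marker score. In epithelium-like cells 6 of 12 were lower (median -0.84, -1.09 to -0.55), with the growth factor gene Igf2 2.75-fold lower (2.14 to 3.57) and Grb10, which restrains insulin signalling, 2.62-fold lower (1.93 to 3.60). Mest was 2.57-fold higher (2.29 to 2.88) in the fibroblast-like cells and 2.06-fold lower (1.54 to 2.78) in the epithelium-like cells, where its log2 ratio of -1.04 was -0.29 with the stricter filter on cells. The medians differed by 1.71, and the fibroblast median lay 1.48 above that of macrophage-like cells, -0.61 (-0.95 to -0.17) over 10 members, 5 of them lower (2 relative to the median gene). In muscle progenitor-like cells 2 of 13 members were higher (median 0.52, 0.47 to 0.68), among them Dlk1, 3.43-fold higher, and Meg3, 2.44-fold higher (2.33 to 2.54). That median lay 1.35 above the one of epithelium-like cells and 1.13 above the one of macrophage-like cells. The epithelium-like cells came mostly from cluster 11 at E15.5 and from cluster 24 at E18.5, so the kinds of epithelium compared are not the same. Cartilage matrix genes were lower in the same cells, 15 of 16 in the epithelium-like class (median -2.80), 16 of 16 in cluster 24 alone (-4.30) and 14 of 14 in macrophage-like cells (-2.74), medians that were -1.49 and -1.77 in the classes with the 3% highest Scrublet scores left out. In the fibroblast-like class 2 were higher and 7 lower of 17 (-0.59), and in cluster 15 1 and 14 of 16 (-1.12). Within single clusters the epithelium median was -1.70 (-1.85 to -1.33, cluster 24) and the fibroblast median 0.17 (0.05 to 0.34, cluster 15; 1 higher and 1 lower of 13), with Mest at -1.09 in the latter, so most of the fibroblast side lay in cluster 27, nearly missing at E15.5. The fibroblast median was 0.46 by highest marker score and 0.24 at Leiden resolution 0.5, where Mest turned to a log2 ratio of -1.07. The macrophage median was -0.05 at Leiden resolution 2.0, -0.11 with the Scrublet calls kept and 0.008 with the 3% highest Scrublet scores left out.

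Limb bud patterning genes had list medians on opposite sides of 0 in cartilage and muscle over the same stages, with few members past the size rule. In chondrocyte-like cells 4 of 15 members were higher (median 0.62, 0.16 to 0.89), including the homeobox genes Msx1, 2.99-fold higher (2.38 to 3.72), and Lhx2, 2.29-fold higher (1.61 to 3.20). In muscle progenitor-like cells 0 of 5 were higher and 0 lower (median -0.61, -1.0 to -0.05), so the medians differed by 1.23, with the muscle side resting on 5 genes. The muscle median was 0.14 with each cell in the class of its highest marker score. The chondrocyte-like cells came mostly from cluster 16 at E15.5 and cluster 26 at E18.5, and in cluster 16 alone 1 of 11 members was higher (median 0.50, 0.01 to 1.00), and Msx1 had a log2 ratio of 0.71 against 1.58 in the class. With only cluster 26 left out 3 of 15 were higher (median 0.31, 0.10 to 0.96).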

How the results depend on the processing

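Of the alternatives, 5 were chosen after the data were seen: leaving out the 3% of cells with the highest Scrublet scores, leaving ribosomal protein and mitochondrial genes out of the totals, centring on transcript length, taking the largest cluster of a class alone, and leaving out of a class the clusters that 1 library nearly lacks. The others were fixed before. A value is called here when a gene passed the size rule relative to the median gene, or when a list's median was at least 1 with an interval on 1 side of 0.

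Of the log2 ratios of named genes and of lists within classes recomputed under an alternative, 2394 lay within the counting interval of the reported value and 531 outside it, and 6 called values changed sign: Mest in connective tissue fibroblast-like cells at E18.5 over E15.5, with a log2 ratio of 1.36, came to -1.07 at Leiden resolution 0.5, where the cause was not tested, and to -1.09 both in the largest cluster alone and without clusters that 1 library nearly lacks, each of which leaves out cluster 27 only. In chondrocyte-like cells of the same pair the largest cluster, 16, alone gave medians of -0.38 for joint genes, 1.09 in the class, and -0.22 for stress genes, 1.19 in the class. With only cluster 26 left out the joint median came to -1.33, so the joint sign rests on that cluster, while the stress median was 0.16, so that median changed sign only with clusters 17 and 23 left out as well; why was not tested. Where an alternative left a class with under 30 cells, it gave no value. For medians of gene lists, 960 values lay within the interval, 223 outside it and 1 changed sign: the mitochondrially encoded genes at E18.5 over E11.5, 1.21 (1.19 to 1.22), came to -0.086 with ratios centred on transcript length, since these genes are short. Among values not called, 25 left their interval for the other side of 0: 14 list medians in the whole library, 6 within classes and 5 ratios of Gdf5 in joint-like cells, reported as 0.59 and between -0.24 and -0.0870 in these cases. The medians within classes were those of G2/M in chondrocyte-like cells, -0.71 and 0.64 in cluster 16 alone, G2/M in joint-like cells, -0.76 and 0.23 at Leiden resolution 0.5 or 0.25 by highest marker score. They were also those of sarcomere genes in differentiating muscle-like cells, -0.50 and 0.49 with libraries clustered separately, patterning in muscle progenitor-like cells, -0.61 and 0.14 by highest marker score, and imprinted growth in macrophage-like cells, -0.61 and 0.008 with the highest Scrublet scores left out; the cause was not tested.

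Clustering each library by itself gave 5.55% epithelium-like and 1.48% muscle-like cells at E11.5, and 42.8% and 35.6% of all cartilage at E13.5 and E15.5. Giving each cell the class of its highest marker score gave 0.608% muscle-like cells at E11.5 and 12.1% at E18.5, 7.04% joint-like cells at E13.5 and 12.3% of all cartilage at E18.5. At Leiden resolution 0.5 joint-like cells at E13.5 were 18.3% and all cartilage at E18.5 20.5%. The stricter cell filter gave 11.1% joint-like cells at E13.5, 50.1%, 55.0% and 18.2% of all cartilage at E13.5, E15.5 and E18.5, and 20.3% muscle-like cells at E18.5. With Scrublet calls kept joint-like cells at E13.5 were 15.3%, and with the 3% highest scores left out muscle-like cells at E11.5 were 0.742%. In all these cases the cause was not tested.

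Scaling moved the counts of genes. With median-of-ratios size factors 2971 genes were higher and 1447 lower at E13.5 over E11.5, and 2058 lower at E18.5 over E11.5, because such factors remove the shift of the median gene. Without ribosomal protein and mitochondrial genes in the totals 2288 and 3323 genes were lower in these pairs, and with centring on transcript length 1544 and 1983. The mean over cells gave 242 genes lower at E15.5 over E13.5; the cause was not tested. Of all recomputed counts of genes, those just given and within-class counts included, 594 were within 1.5 times the reported ones and 84 were not. Shares of cells with a UMI lay outside their interval in 119 of the recomputed cases, 58 of them without thinning and 51 at 1000 UMIs, since a share depends on depth by construction.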

Other observations

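The tests in this part that were chosen only after the result was seen are those of transcript length in endothelium-like and epithelium-like cells, of class shares outside cartilage, of the pericyte genes in the library sums, and of stress genes in parts of a class. The single genes given next were also chosen after their values were seen. Some genes known from glia and muscle were found in cartilage-like cells above their level in endothelium-like cells, though not in each class and stage. Mbp, a myelin gene, stood at 27.5 CPM in hypertrophic chondrocyte-like cells at E13.5, 16.1 times the level in endothelium-like cells (4.35 to 135), and the slow troponin gene Tnni1 at 78.5 CPM, 11.5 times (5.77 to 26.9). Fabp7, a lipid carrier of glia, was 27.6 times higher in chondrocyte-like than in endothelium-like cells at E15.5 (4.92 to 1094), and Sox10, the regulator of neural crest, 4.11 times (1.11 to 34.4). Other cases had intervals that span 1: in chondrocyte-like cells Mbp stood at 1.97 times (0.523 to 16.7) the endothelial level at E13.5 and 0.846 times (0.207 to 7.44) at E15.5 and Tnni1 at 0.984 times (0.5 to 2.21) at E15.5, and in hypertrophic chondrocyte-like cells Sox10 at 1.24 times (0.452 to 4.23) at E13.5 and 4.25 times (0.987 to 38.2) at E15.5. The joint lubricant gene Prg4 and Ucma had 91.6% and 92.0% of their UMIs at E18.5 in the same chondrocyte-like cluster of 205 cells, which also held 80.3% of Gdf5.

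Small groups of cells carried other genes of the report. At E15.5 51 cells of an unnamed cluster led by Cpa3 held 97.0% of the 3713 UMIs of Cma1, and 40 cells of the lymphatic endothelium-like cluster 98.0% of those of Ccl21a. Krt4 at E15.5 had 85.8% of its 1332 UMIs in 7 cells of an epithelium-like cluster led by Krt8, Krt19 and Krt18, and S100a8 at E18.5 had 75.5% of 40249 UMIs in 51 cells.

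Short transcripts were low at E11.5, in the whole library and in both classes compared with E13.5. Among genes outside the ribosomal protein and mitochondrial ones, those under 1000 nt lay 1.83 above those of at least 1500 nt in the log2 ratio of E13.5 over E11.5 in endothelium-like cells and 1.91 in epithelium-like cells, which argues against lower ribosomal protein expression as the whole cause. With ribosomal protein and mitochondrial genes out of the totals the median gene still lay at -0.26, so those genes do not account for the whole shift. A loss of short transcripts when the E11.5 library was made may explain the pattern, and stage, which coincides with library, stays open as a biological cause.

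The cartilage share was low at E18.5 and the pericyte and muscle shares were high. A lower yield of cartilage cells alone raises all other classes alike, but outside cartilage the share of pericyte-like cells was 20 times that of E15.5 (11.5 to 38.0) and that of endothelium-like cells 0.322 times (0.224 to 0.456), 62.1 times apart. The pericyte list also had a median log2 ratio of 3.88 in CPM in the library sums, which use no clusters. That list holds the same genes as the marker list that named the pericyte-like class. A change of these genes in the E18.5 library would raise both the sums and the share. The sums therefore cannot decide whether clusters that follow the library are the cause. Digestion that frees classes unequally at E18.5 was not tested and could contribute, as could growth of muscle between the stages.

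The median of the stress list and the chemokine genes Cxcl1, Ccl2 and Cxcl2, taken from the highest ratios, were high at E18.5. Most members of the stress list did not pass the size rule in the library sums. The median log2 ratio of the immediate early and heat shock list in CPM at E18.5 over E15.5 was at least 0.46 in each class compared, the lowest being differentiating muscle-like cells, as a response of all cells to handling would give. In chondrocyte-like cluster 16 alone it was -0.17 (-0.34 to 0.03, 31 cells at E18.5), or -0.22 (-0.39 to -0.02) relative to the median gene, which goes against it, and with only cluster 26 left out 0.19 (0.08 to 0.42), but clusters are not the classes compared and heat shock genes are among the leading genes of cluster 26, so the explanation stays open. Free RNA from pericyte-like cells is argued against for Cxcl1 and Ccl2: per Rgs5 UMI, connective tissue fibroblast-like cells had 4.36 times as much Cxcl1 as pericyte-like cells (3.5 to 5.52), and 6.42 times as much Ccl2, while Cxcl2, with 47.0% of its UMIs in macrophage-like cells, decides nothing. Stage, handling and the arrival of immune cells remain open as causes.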
